A study of Mus musculus with 20 samples.

How the data were processed

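Per the labels, total RNA of primary cortical neurons from fetal Swiss albino mice (gestational day 15 or 16, day 7 of culture) was labelled as biotinylated cRNA and hybridised to Illumina MouseRef-8 v1.1 bead arrays. Hypoxia (oxygen partial pressure below 50 mm Hg) was held for 10 min, 5 h, 8 h, 15 h or 24 h. The design has 20 arrays on 3 slides: 5 controls and 3 arrays for each time. Labels give a replicate number but not the source of the replicates, and the numbers were not used to pair samples.

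The deposited BeadStudio 3.1.7 profile holds, for 24620 probes and each array, the average signal as an intensity that was not normalized, and the detection value as a score, 1 minus the detection p. Per the file headers, 8 columns describe each array, and the 120 columns that give bead numbers, standard deviations, array numbers and lowest and highest signals were not used. The authors also provided a non-normalized table with the same average signal as intensity, and normalized tables whose values are a ratio: each intensity divided by the median of its array and then by the median of the controls. This was checked on 24607 probes, of which 24607 had a control median of 1 within a tolerance of 1e-05. The 5 control columns of these tables hold the values of another control array than the label at that position, so arrays were named by the profile.

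Row names differ between the profile and the processed tables: of 24601 rows with the values of 1 profile probe, 2 carried the same identifier. Identifiers of the processed tables were paired through identical values (24167 pairs) with those of the platform table, whose annotation gave gene symbols. The profile's own identifier was looked up through these pairs. Of 10748 paired identifiers that hold a number of the form of a gene number, 7482 held the annotated one, against 1 after shuffling. The others disagreed, and why was not tested. With the profile's names, the 2 probes of 3615 genes correlated at 0.337 in mean signal, against 0.062 for 3614 genes with the other names. Profile names gave Actb and Gapdh a mean signal of 13474.4 and 12431.7, and the other names gave 46.2 and 448. Other genes were less clear: with the profile's names Tubb3 read 245.1 against 1790.4, Snap25 52 against 42.7, Eef1a1 185.7 against 46.1 and Rplp0 480 against 51.3. Every result for a named gene rests on this choice. The profile's names were used throughout. In all 20614 probes were named, for 15785 genes, and 4006 were not.

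After 7 bacterial control probes were left out, the intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (offset 16) and put on the log2 scale. Probes with a detection p under 0.01 on at least 3 of the 20 arrays were kept: 10447, of which 9120 were named, for 7721 genes. A linear model with 6 groups was fitted over all arrays, with limma's moderated tests (two-sided), and p-values were adjusted within each comparison by the Benjamini-Hochberg method at 0.05. Each time was compared with the controls and each later time with the one before, except 5 h with 10 min, since the slide of the 10 min arrays holds 1 control. The median SE was 0.122 against the controls and 0.136 between times.

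Before the data were examined, 25 gene lists, the comparisons, a rule for naming genes and the alternatives not marked as added later were fixed. The rule named the 8 largest rises and falls per time and 5 between times, among probes past the test whose arrays all lay outside the range of the other group, the 4 members with the smallest adjusted p of each list that passed, and 8 genes at every time; a gene that was not detected in a group is given as a bound on its fold change. Lists were tested with camera with a preset correlation of 0.01 between genes, using the probe with the highest mean for each gene, and again with an estimated correlation and with fry, and p-values were adjusted over the lists of a comparison. They hold hypoxia targets, glycolytic enzymes, the ATF4 and amino acid response, endoplasmic reticulum chaperones, heat shock proteins, antioxidant and NRF2 targets, immediate early and activity genes, apoptosis and p53 targets, cell cycle, synaptic vesicle genes, receptors and postsynaptic genes, neuronal cytoskeleton, interneuron, astrocyte, oligodendrocyte, microglia, vascular and fibroblast, and progenitor markers, oxidative phosphorylation, cholesterol synthesis, proteasome, inflammatory genes, autophagy and lysosome, calcium handling and calpains, and ribosomal proteins. Of the 8 genes, 6 were measured: Bnip3 was not detected often enough to be tested and Hspa1b had no named probe.

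Alternatives were slide as a fixed or random block, slide-matched controls, a replicate block, the authors' normalized values, other normalizations and filters, array weights, other settings of the moderation, fits of only the groups compared, other thresholds and leaving out each array. Slide as a fixed block and slide-matched controls are the same model in this layout. Every split of the arrays of a comparison into groups of the same sizes was refitted. The procedure was tested on simulated data with 200 of 10447 probes changed: at 15 h, 62.7% of 1.5-fold and 98.5% of 2-fold changes were recovered and 6 of 10247 unchanged probes called, at 8 h 70.1%, 97% and 10, and at 24 h against 15 h 53.7%, 94% and 4. The simulated noise was independent for each probe, had the same spread in every group and held no array shifted across many probes. These rates therefore do not give the rate of false calls in the real arrays.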

Results

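RNA from mouse primary cortical neurons was measured on 20 single-colour bead arrays. The neurons came from fetal cortices at gestational day 15 or 16 and had been 7 days in culture. Oxygen-glucose deprivation (OGD), a culture model of the loss of oxygen and glucose in stroke, was held for 10 min, 5 h, 8 h, 15 h or 24 h, with 3 arrays per time and 5 untreated control arrays. Median signal per array lay between 53.1 and 65.4, and 37% to 40.9% of the probes were detected. The arrays lay on 3 slides. The first held control replicate 1 and the 10 min arrays, the second controls 4 and 5 with the 5 h and 8 h arrays, and the third controls 2 and 3 with the 15 h and 24 h arrays. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

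The design asks how neuronal transcripts differ after each length of OGD and how successive times differ. Of 10447 probes tested, 5693 differed in the moderated F test over the 5 times. The first principal component held 52% of the variance and placed the 10 min, 15 h and 24 h arrays on 1 side and the 5 h and 8 h arrays on the other. Control replicate 2 lay with the 10 min, 15 h and 24 h arrays at 9.7, and the other 4 controls lay between -24.9 and -14.7. Across probes, the deviations of control replicate 2 correlated at 0.41 to 0.47 with those of the 10 min arrays and at -0.49 to -0.24 with those of the other controls. Among the 5 h and 8 h arrays, 8 h replicate 3 correlated across probes at 0.06 and 0.24 with the other 8 h arrays and at 0.64 with 5 h replicate 1. These 2 arrays lay at -22.5 and -19.3 on the third component, against 2.3 to 9.8 for the other arrays of both times, and without them, an alternative chosen after this was seen, 245 probes passed at 5 h, 0 at 8 h and 97 for 8 h against 5 h. The median SD over probes was 0.196 among the controls and 0.102 to 0.143 within the times. Control arrays on the third slide differed from those on the second in 0 probes in limma's test, with 296 at an unadjusted p under 0.05 and 2 residual degrees of freedom.

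**Figure D1:**
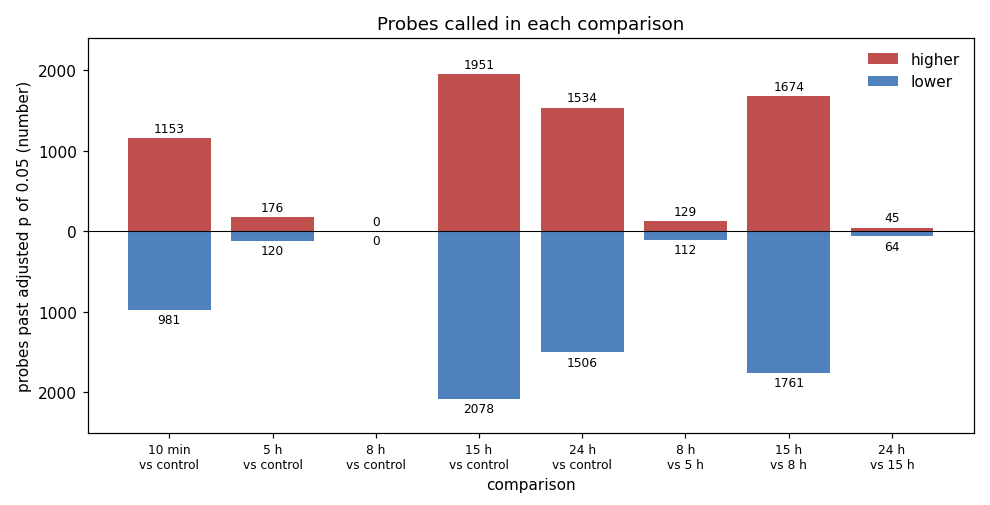
Number of probes higher (above 0) and lower (below 0) in each comparison at an adjusted p under 0.05, of 10447 tested, without the slide as a block. The most probes passed at 15 h, 1951 higher and 2078 lower, and none at 8 h. With the slide as a block, which is not drawn, none passed at 5 h either.

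After 10 min of OGD, transcripts of activity-induced transcription factors, of the ATF4 amino acid response and of cholesterol synthesis were lower than in the controls, and markers of astrocytes, microglia and neural progenitors were higher, in tests of lists with a preset correlation between genes. All of these lists lost the call at adjusted p = 0.121 to 0.24 with an estimated correlation, and the astrocyte and progenitor lists also with the slide as a block (adjusted p = 0.102 and 0.0685). The leading rise was that of Bdh2 (probe 1770397), which encodes a hydroxybutyrate dehydrogenase, by 2.29 ± 0.41 on the log2 scale (SE, n = 3 against 5, adjusted p = 0.00119), or 4.89-fold. Rnase1, a secreted ribonuclease, rose 3.73-fold, the chemokine gene Ccl9 rose 3.53-fold and Acta2, smooth muscle actin, rose 3.46-fold. Pvalb, the calcium-binding parvalbumin, rose by 1.72, the lipid droplet coat gene Plin4 by 1.66, the glutathione transferase gene Gstt3 by 1.64 and the cytochrome oxidase subunit gene Cox8b by 1.62. Fosb, an activity-induced partner of Jun proteins, was not detected on any 10 min array and was at least 4.01-fold lower (adjusted p = 0.000208). Egr4 and Npas4, transcription factors induced by neuronal activity, changed by -2.11 ± 0.28 and -1.75 ± 0.21 (SE). Atf5, a transcription factor of the stress response, changed by -1.61, the amino acid transporter gene Slc7a5 by -1.49, the matrix proteoglycan gene Dcn by -1.51 and C2cd4a by -1.68. Pop4, a subunit of ribonuclease P, was not detected at 10 min and was at least 29.6-fold lower (adjusted p = 0.00722, 0.0974 with the slide as a block), but its probe also read near background on single arrays of later times. Of the 5 controls, Ccl9 and Plin4 were detected on 1, Pvalb on 2, Cox8b on 3 and Rnase1 and Gstt3 on 4. These rises are thus over a level partly at background, and Npas4 was detected on 2 of the 3 arrays at 10 min. Control replicate 2 lay apart from the other controls, toward the 10 min arrays, on Ccl9, Acta2, Plin4, Gstt3, Npas4, C2cd4a, Atf5, Dcn and Slc7a5. For Fosb it read 5.46, against 7.46 to 8.34 on the other controls and 4.52 to 4.67 on the 10 min arrays. For Ccl9 it read 6.02 against a mean of 4.43 on the other controls. Bdh2 was also above the control mean on this array, so an untreated array carried part of these differences.

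Of the 23 measured genes of the ATF4 and amino acid response, 20 fell and 0 rose at 10 min (21 and 1 adjusted over the list alone). Their median was -0.82 (camera adjusted p = 2.15e-13, and adjusted p = 0.234 with an estimated correlation). Besides Atf5 and Slc7a5, the alanyl-tRNA synthetase gene Aars changed by -0.82 and the asparagine synthetase gene Asns by -1.24. With the slide as a block the list's median was -1.17 (adjusted p = 4.39e-14). On this list's mean, control replicate 2 lay at -0.76 from the control mean, and the other controls at 0.11 to 0.24. Cholesterol synthesis genes fell in 13 of 17 (14 adjusted over the list alone). Their median was -0.64 (adjusted p = 1.93e-07, adjusted p = 0.24 with an estimated correlation, and 0.0018 with a median of -0.50 with the block). Among them the farnesyl diphosphate synthase gene Fdps changed by -0.91, the lanosterol synthase gene Lss by -0.86, Nsdhl by -0.89 and Hmgcs1 by -0.47, and control replicate 2 lay at -0.52 on the list's mean. Immediate early and activity genes fell in 12 of 23 (13 adjusted over the list alone). Among them Nptx2 changed by -1.30 and Junb by -1.42. The median of the list was -0.49 (adjusted p = 2.81e-07, adjusted p = 0.234 with an estimated correlation, and 0.00171 with a median of -0.43 with the block), and control replicate 2 lay at -0.36.

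Markers of astrocytes and microglia moved the other way at 10 min. Of 16 astrocyte markers 8 rose (9 adjusted over the list alone), among them Clu and Glul, each by 0.85, Apoe by 0.84 and the intermediate filament gene Gfap by 0.79. The median of the list was 0.30 (adjusted p = 0.000516, adjusted p = 0.24 with an estimated correlation, and 0.102 with a median of 0.18 with the block), with control replicate 2 at 0.19. Of 9 microglia and macrophage markers 5 rose (7 adjusted over the list alone). Among them the growth factor gene Csf1 rose by 0.59, the galectin gene Lgals3 by 0.71 and Adgre1 by 0.45. The median of the list was 0.43 (adjusted p = 0.000364, adjusted p = 0.234 with an estimated correlation, and 0.006 with a median of 0.39 with the block), and control replicate 2 lay at 0.14. Trem2, detected on 1 of the 3 arrays at 10 min and on no control, was at least 1.03-fold higher, and Adgre1 was detected on 2 of 5 controls. Of 11 neural progenitor markers 4 rose (6 adjusted over the list alone). Among them Prom1 rose by 0.92, Id4 by 0.72, Id1 by 0.54 and Notch1 by 0.34 (median 0.26, adjusted p = 0.00517, adjusted p = 0.121 with an estimated correlation, and 0.0685 with a median of 0.22 with the block).

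Lists of neuronal cytoskeleton and receptor genes were also lower at 10 min with the preset correlation (adjusted p = 0.24 for each with an estimated correlation). Of 25 genes of the neuronal cytoskeleton and projections 6 fell (6 adjusted over the list alone), among them the transcription factor genes Neurod2 by -0.69 and Bcl11b by -0.55, the RNA-binding protein gene Elavl3 by -0.79 and Tubb3 by -0.41 (median -0.24, adjusted p = 0.00265, adjusted p = 0.24 with an estimated correlation, and 0.102 with a median of -0.17 with the block). Of 16 receptor and postsynaptic genes 4 fell (5 adjusted over the list alone). Among them the glutamate receptor genes Gria1 changed by -0.80 and Grik1 by -0.41, the kinase gene Camk2a by -0.67 and the scaffold gene Shank3 by -0.42 (median -0.24, adjusted p = 0.0206, adjusted p = 0.24 with an estimated correlation, and 0.102 with a median of -0.19 with the block). Endoplasmic reticulum chaperones fell in 6 of 16 and rose in 0 (7 and 1 adjusted over the list alone). Among them Hspa5 changed by -0.72, Sec61a1 by -0.48, Hyou1 by -0.47 and P4hb by -0.34 (median -0.21, adjusted p = 0.0161, adjusted p = 0.24 with an estimated correlation, and 0.289 with a median of -0.17 with the block). Of 9 oligodendrocyte markers 3 fell (4 adjusted over the list alone): Cldn11 by -1.62, the myelin gene Mbp by -0.49 and Ugt8a, at least 1.25-fold lower (median -0.24, adjusted p = 0.0311, adjusted p = 0.24 with an estimated correlation, and 0.0426 with a median of -0.33 with the block). At 10 min Hyou1 was detected on 1 and Cldn11 on 2 of the 3 arrays, and Ugt8a on 4 of 5 controls. On these 4 lists control replicate 2 lay at -0.18, -0.14, -0.13 and -0.30. Of the genes followed at every time, Vegfa, the vascular growth factor, changed by -0.60, the heme oxygenase gene Hmox1 by -1.33, Fos by -1.37, Ddit3 by -0.55 and the cell cycle inhibitor Cdkn1a by -0.78 (adjusted p = 0.00284, 0.000423, 0.000635, 0.00894 and 0.00613), and the glucose transporter gene Slc2a1 differed by 0.45 (adjusted p = 0.0723). The hypoxia list had a median of 0.03 (4 of 23 higher and 4 lower, 7 and 5 adjusted over the list alone, adjusted p = 0.848).

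In all, 1153 probes were higher and 981 lower at 10 min (limma, adjusted p under 0.05), for 963 and 800 genes, of which 76 and 40 probes differed at least 2-fold. With the slide as a block, which here rests on control replicate 1 alone, 564 were higher and 672 lower, and 749 of these were shared with the fit without it. Among the genes named above, Pop4, Sec61a1, Hspa5, Hyou1, P4hb, Camk2a, Shank3, Grik1, Tubb3, Glul, Ugt8a, Csf1, Lgals3, Trem2, Id1, Notch1, Fdps, Nsdhl, Vegfa and Cdkn1a no longer passed with the block (adjusted p = 0.0506 to 0.587). The authors' normalized values gave 1230 higher and 554 lower. Without control replicate 2 the count was 3532, and without any 1 of the 10 min arrays or control replicates 3 or 5 it was 1111 to 1372.

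After 5 h of OGD, histone genes led the falls against the controls, with 18 of 39 histone probes lower. Single genes such as Crebbp, Hk1 and Nf1 were higher. The histone group was chosen after the leading genes had been seen and was not tested as a list. With the slide as a block no probe passed. The linker histone gene H1f2 changed by -1.80 ± 0.30 on the log2 scale (SE, n = 3 against 5, adjusted p = 0.00477), a 3.48-fold difference. The H2B histone genes H2bc7, H2bc9, H2bc11, H2bc15, H2bc13 and H2bc22 changed by -1.63, -1.59, -1.52, -1.39, -1.38 and -1.37, and Thrsp, a regulator of lipid synthesis, by -1.22. The controls were split for H1f2, with 12.04, 12.58 and 11.99 on replicates 1, 2 and 4 and 10.74 and 10.67 on replicates 3 and 5, against 10.11, 9.70 and 9.60 on the 5 h arrays, so the size of the fall depends on that split. Crebbp, a histone acetyltransferase, rose 2.01-fold by its leading probe (1.01 on the log2 scale, another probe 0.43), the hexokinase gene Hk1 1.84-fold, and Atrnl1, the differentiation inhibitor Eid1 and the neurofibromin gene Nf1 1.77-fold each. Crebbp, Hk1 and Atrnl1 were detected on 2, 3 and 4 of 5 controls. Stmn1, which destabilises microtubules, rose by 0.80, the chromatin protein gene Hmgb1 by 0.75 and the chaperone gene Hspa5 by 0.74.

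Cholesterol synthesis genes were shifted upward at 5 h as a list, with a median of 0.36 (adjusted p = 6.4e-05, adjusted p = 0.449 with an estimated correlation, and 0.0532 with a median of 0.22 with the block), although 0 of 17 passed singly (5 rose adjusted over the list alone). The ATF4 and amino acid list had a median of 0.25 with 0 of 23 past the test (0 adjusted over the list alone, adjusted p = 0.0123, adjusted p = 0.454 with an estimated correlation, and 0.381 with a median of 0.10 with the block). The antioxidant and NRF2 list had a median of -0.19 (adjusted p = 0.00464, adjusted p = 0.449 with an estimated correlation, and 0.146 with a median of -0.10 with the block), and 1 of 22 members fell (4 adjusted over the list alone), the ferritin gene Fth1 by -0.57. On these 3 lists control replicate 2 lay at -0.52, -0.76 and 0.36 from the control mean. On the ATF4 list the 5 h arrays lay at 0.342, 0.189 and 0.181, against 0.244, 0.186, 0.114 and 0.211 on controls 1, 3, 4 and 5. The upward shift of that list thus rests largely on control replicate 2. On the antioxidant list the 5 h arrays lay at -0.225, -0.265 and -0.3, about the level of controls 3 and 5 (-0.277 and -0.286). Controls 1 and 4 lay at 0.077 and 0.123. The 3 lists did not pass in fry (adjusted p = 0.113, 0.217 and 0.123). Cdkn1a changed by -0.68 (adjusted p = 0.0489, 0.238 with the slide as a block), and another Cdkn1a probe read -0.14. Vegfa, Slc2a1, Hmox1, Fos and Ddit3 differed by 0.32, -0.44, -0.50, 0.44 and -0.17 (adjusted p = 0.146, 0.154, 0.165, 0.255 and 0.469), and the hypoxia list had a median of 0.03 (adjusted p = 0.131).

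At 5 h, 176 probes were higher and 120 lower (143 and 111 genes). With the slide as a block 0 passed, where 2281 had passed an unadjusted p under 0.05 without it, and a random block for the slide left 84. The split of calls moved with the scaling, to 142 higher and 181 lower with 75th-percentile scaling and 895 and 46 with the authors' normalized values. Without 5 h replicates 1, 2 or 3 the counts were 189, 27 and 35, and without control replicate 5 it was 551.

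After 8 h of OGD no probe differed from the controls in limma's test, while 668 passed at an unadjusted p under 0.05. Several gene lists were shifted by small amounts. The hypoxia-inducible genes had a median of 0.08 (adjusted p = 0.00716, adjusted p = 0.142 with an estimated correlation, and 0.0214 with a median of 0.08 with the block) and the glycolytic enzymes one of 0.16 (adjusted p = 0.00716, adjusted p = 0.33 with an estimated correlation, and 0.0214 with a median of 0.18 with the block). Oligodendrocyte markers had a median of 0.19 (adjusted p = 0.00773, adjusted p = 0.188 with an estimated correlation, and 0.177 with a median of 0.13 with the block). Genes of oxidative phosphorylation, the mitochondrial respiratory chain, had a median of -0.10 (adjusted p = 3.82e-05, adjusted p = 0.0767 with an estimated correlation, and 0.000472 with a median of -0.11 with the block). Synaptic vesicle genes had a median of -0.12 (adjusted p = 0.00716, adjusted p = 0.45 with an estimated correlation, and 0.00468 with a median of -0.10 with the block) and receptor and postsynaptic genes one of -0.08 (adjusted p = 0.0198, adjusted p = 0.337 with an estimated correlation, and 0.00468 with a median of -0.17 with the block). Adjusted over the list alone, 1 of 13 glycolytic enzymes and 2 of 9 oligodendrocyte markers rose, and 0 members of the other 4 lists passed. In fry only oxidative phosphorylation passed of these 6 lists, and the others had an adjusted p = 0.0804 to 0.428.

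Of the genes followed at every time, Hmox1 differed by 0.59, Slc2a1 by 0.42, Cdkn1a by -0.20, Ddit3 by -0.15, Vegfa by -0.06 and Fos by 0.01 at 8 h (adjusted p = 0.749, 0.772, 0.885, 0.884, 0.959 and 0.994). With the slide as a block, 3 more lists were shifted at 8 h: ATF4 genes by a median of -0.19, antioxidant genes by 0.17 and neuronal cytoskeleton genes by -0.17 (adjusted p = 0.000472, 0.00468 and 0.00647). Without the block these lists had adjusted p = 0.935, 0.782 and 0.782 with an estimated correlation, and 0.417, 0.133 and 0.133 with the preset correlation. Leaving out control replicate 2 alone also gave these calls (adjusted p = 2.39e-10, 0.000513 and 0.0075). The cytoskeleton list also passed camera with 75th-percentile scaling and with the authors' normalized values (adjusted p = 0.0165 and 0.0231). The absence of these calls thus depends on that array, on how the slide is modelled and, for the cytoskeleton list, on the scaling. The count of probes stayed at 0 with the block, and it was 1 without control replicate 4. Array weights gave 584 probes.

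After 15 h of OGD, antioxidant genes, astrocyte and microglia markers and inflammatory genes were higher than in the controls, and synaptic, activity-induced and cholesterol synthesis genes were lower, in tests of lists with a preset correlation. With an estimated correlation the progenitor list alone passed. Bdh2 rose by 2.72 ± 0.41 on the log2 scale (SE, n = 3 against 5, adjusted p = 4.4e-05), or 6.59-fold, Plin4 6.41-fold, Rnase1 5.74-fold and Pvalb 5.66-fold. Dbp, a clock-controlled transcription factor, rose by 2.48 ± 0.39 (SE), and the conjugating enzyme genes Ugt1a7c and Gsta3 by 2.44 and 2.34. Psmc1, a proteasome ATPase, read 2.54 ± 0.65 (SE) higher by a probe that varied widely within most other times. Fosb was not detected at 15 h and was at least 4.16-fold lower, and a Dcn probe likewise at least 3.79-fold lower. On control replicate 2 Fosb read 5.46, against 7.46 to 8.34 on the other controls and 4.56 to 4.84 at 15 h. C2cd4a changed by -2.20, the epidermal protein gene Lor by -1.89, Egr4 by -1.88, the sulfotransferase gene Chst8 by -1.84, the neuropeptide gene Nts by -1.71 and the chemokine receptor gene Ackr1 by -1.68. Of the 5 controls, Plin4 was detected on 1, Pvalb on 2, Gsta3 on 3 and Rnase1 on 4. For Bdh2 control replicate 2 lay at 9.21 against 7.42 ± 1.18 (SD, n = 5) for the controls and 10.13 ± 0.11 (SD, n = 3) at 15 h.

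Antioxidant and NRF2 targets rose in 20 of 22 measured genes at 15 h (20 adjusted over the list alone). Their median was 0.93 (adjusted p = 7.18e-11, adjusted p = 0.0705 with an estimated correlation, and 6.18e-11 with a median of 0.78 with the block). The metallothionein gene Mt2 rose by 2.03, glutathione reductase Gsr by 1.45, Gclm, a subunit of the enzyme that starts glutathione synthesis, by 1.22 and Gstm5 by 0.68, and control replicate 2 lay at 0.36 on the list's mean. Astrocyte markers rose in 14 of 16 and fell in 1 (14 and 1 adjusted over the list alone). Their median was 0.60 (adjusted p = 1.02e-06, adjusted p = 0.0762 with an estimated correlation, and 1.21e-06 with a median of 0.64 with the block). Among them Vim rose by 0.95, Apoe by 0.88, Clu by 0.85 and Mlc1 by 0.74. Microglia and macrophage markers rose in 8 of 9 (9 adjusted over the list alone). Their median was 0.70 (adjusted p = 5.7e-05, adjusted p = 0.0705 with an estimated correlation, and 0.000135 with a median of 0.60 with the block). Among them Lgals3 rose by 1.25, the complement gene C1qc by 0.97, Csf1 by 0.83 and Adgre1 by 0.71. Neural progenitor markers rose in 6 of 11 (8 adjusted over the list alone). Their median was 0.38 (adjusted p = 0.000318, adjusted p = 0.0283 with an estimated correlation, and 0.000204 with a median of 0.54 with the block). Among them Prom1 rose by 1.16, Notch1 by 1.15, Id4 by 0.88 and Nes by 0.62. Inflammatory genes rose in 6 of 10 (6 adjusted over the list alone). Their median was 0.53 (adjusted p = 0.00107, adjusted p = 0.0705 with an estimated correlation, and 0.00105 with a median of 0.48 with the block). Among them the chemokine gene Ccl4 rose by 1.07, the adhesion molecule gene Vcam1 by 0.71 and Il18 by 0.52, and Ccl3 was at least 1.24-fold higher. Adgre1 and C1qc were detected on 2 of 5 controls, Ccl4 on 3, Mlc1 on 4 and Ccl3 on 0. On the means of the astrocyte, microglia, progenitor and inflammatory lists control replicate 2 lay at 0.19, 0.14, -0.01 and 0.05.

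Synaptic vesicle and release genes fell in 18 of 22 at 15 h (19 adjusted over the list alone). Their median was -0.68 (adjusted p = 1.06e-08, adjusted p = 0.0705 with an estimated correlation, and 9.26e-10 with a median of -0.64 with the block). The vesicular glutamate transporter gene Slc17a7 changed by -1.54, the dynamin gene Dnm1 by -1.02, the syntaxin gene Stx1a by -0.89 and the complexin gene Cplx1 by -0.84, and control replicate 2 lay at -0.02 on the list's mean. Neuronal cytoskeleton and projection genes fell in 16 of 25 and rose in 1 (17 and 1 adjusted over the list alone). Their median was -0.41 (adjusted p = 1.59e-05, adjusted p = 0.0705 with an estimated correlation, and 9.38e-05 with a median of -0.35 with the block). Among them the neurofilament gene Nefm changed by -1.01, Crmp1 by -0.96, Dpysl3 by -0.88 and Stmn3 by -0.84. Receptor and postsynaptic genes fell in 8 of 16 and rose in 1 (10 and 2 adjusted over the list alone). Their median was -0.43 (adjusted p = 0.00209, adjusted p = 0.101 with an estimated correlation, and 0.0128 with a median of -0.36 with the block). Among them the calmodulin-binding gene Nrgn changed by -1.67, Camk2a by -1.09, Camk2b by -0.83 and Shank3 by -0.78. Immediate early and activity genes fell in 16 of 23 and rose in 0 (17 and 1 adjusted over the list alone). Their median was -0.71 (adjusted p = 2.2e-06, adjusted p = 0.0762 with an estimated correlation, and 9.97e-06 with a median of -0.60 with the block). Among them Npas4 changed by -1.57, Nptx2 by -1.37, Fosl2 by -1.11 and the scaffold gene Homer1 by -0.71. On the cytoskeleton, receptor and activity lists control replicate 2 lay at -0.18, -0.14 and -0.36.

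Cholesterol synthesis genes fell in 15 of 17 at 15 h (15 adjusted over the list alone). Their median was -0.79 (adjusted p = 1.02e-06, adjusted p = 0.175 with an estimated correlation, and 9.97e-06 with a median of -0.71 with the block). Among them the mevalonate pathway genes Mvd, Fdps and Pmvk changed by -1.37, -1.30 and -0.78, and Lss by -1.22. In the ATF4 and amino acid list 13 of 23 fell and 2 rose (14 and 2 adjusted over the list alone). The median of the list was -0.60 (adjusted p = 0.00107, adjusted p = 0.436 with an estimated correlation, and 0.108 with a median of -0.23 with the block). Asns changed by -1.49, Aars by -0.95 and the asparaginyl-tRNA synthetase gene Nars by -0.89, whereas Slc7a11, the cystine importer of glutathione synthesis, rose by 1.14. Cell cycle genes fell in 11 of 27 and rose in 1 (11 and 1 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.0304, adjusted p = 0.507 with an estimated correlation, and 0.379 with a median of -0.16 with the block). Among them Aurka changed by -0.92, Mcm5 by -0.73 and E2f1 by -0.51, and Cdc25c, detected on 4 of 5 controls and not at 15 h, was at least 1.18-fold lower. On these 3 lists control replicate 2 lay at -0.52, -0.76 and -0.53. Autophagy and lysosome genes rose in 10 of 22 and fell in 5 (10 and 5 adjusted over the list alone). Their median was 0.17 (adjusted p = 0.0304, adjusted p = 0.0705 with an estimated correlation, and 0.0289 with a median of 0.27 with the block). Among them Wipi1 rose by 1.28 and the lysosomal genes Ctsd by 0.99, Lamp2 by 0.91 and Hexa by 0.68. Apoptosis and p53 genes rose in 6 of 20 and fell in 1 (6 and 1 adjusted over the list alone). Their median was 0.13 (adjusted p = 0.0304, adjusted p = 0.0705 with an estimated correlation, and 0.041 with a median of 0.12 with the block). Among them the caspase gene Casp6 rose by 0.97, Ccng1 by 0.87, Phlda3 by 0.65 and the antiapoptotic gene Bcl2 by 0.59, while other Bcl2 probes read 0.08, 0.56 and 0.40. On the autophagy and apoptosis lists control replicate 2 lay at 0.02 and 0.06.

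Slc2a1 rose by 1.10, Hmox1 rose by 1.02 and Fos changed by -1.16 at 15 h (adjusted p = 7.34e-05, 0.000615 and 0.000428), and Vegfa, Ddit3 and Cdkn1a differed by -0.23, -0.30 and -0.09 (adjusted p = 0.154, 0.0876 and 0.739). The hypoxia list had a median of 0.20 (5 of 23 higher and 5 lower, 8 and 5 adjusted over the list alone, adjusted p = 0.278), and passed as raised in fry (adjusted p = 0.0155). In all, 1951 probes were higher and 2078 lower (1587 and 1657 genes), of which 245 and 128 differed at least 2-fold. A slide block gave 1463 and 1467, and 2640 of these were shared, while Bcl2, Mcm5, Cdc25c and Aurka no longer passed (adjusted p = 0.0503, 0.0532, 0.0648 and 0.0546). The authors' normalized values gave 1391 higher and 2412 lower. For 9 lists that did not pass at 15 h the medians were -0.17 for glycolytic enzymes, -0.10 for endoplasmic reticulum chaperones, -0.04 for heat shock proteins, -0.23 for interneuron markers, -0.17 for oligodendrocyte markers, 0.26 for vascular and fibroblast markers, 0.03 for the proteasome, -0.29 for calcium handling and calpains and 0.05 for ribosomal proteins (adjusted p = 0.573, 0.601, 0.601, 0.365, 0.136, 0.529, 0.529, 0.152 and 0.252). In fry the interneuron, oligodendrocyte and calcium lists passed as lower (adjusted p = 0.0138, 0.000462 and 0.0091) and the vascular and ribosomal lists as higher (adjusted p = 0.0115 and 0.0119). Without the filter the oligodendrocyte and calcium lists also passed camera (adjusted p = 0.0293 and 0.0158).

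**Figure D2:**
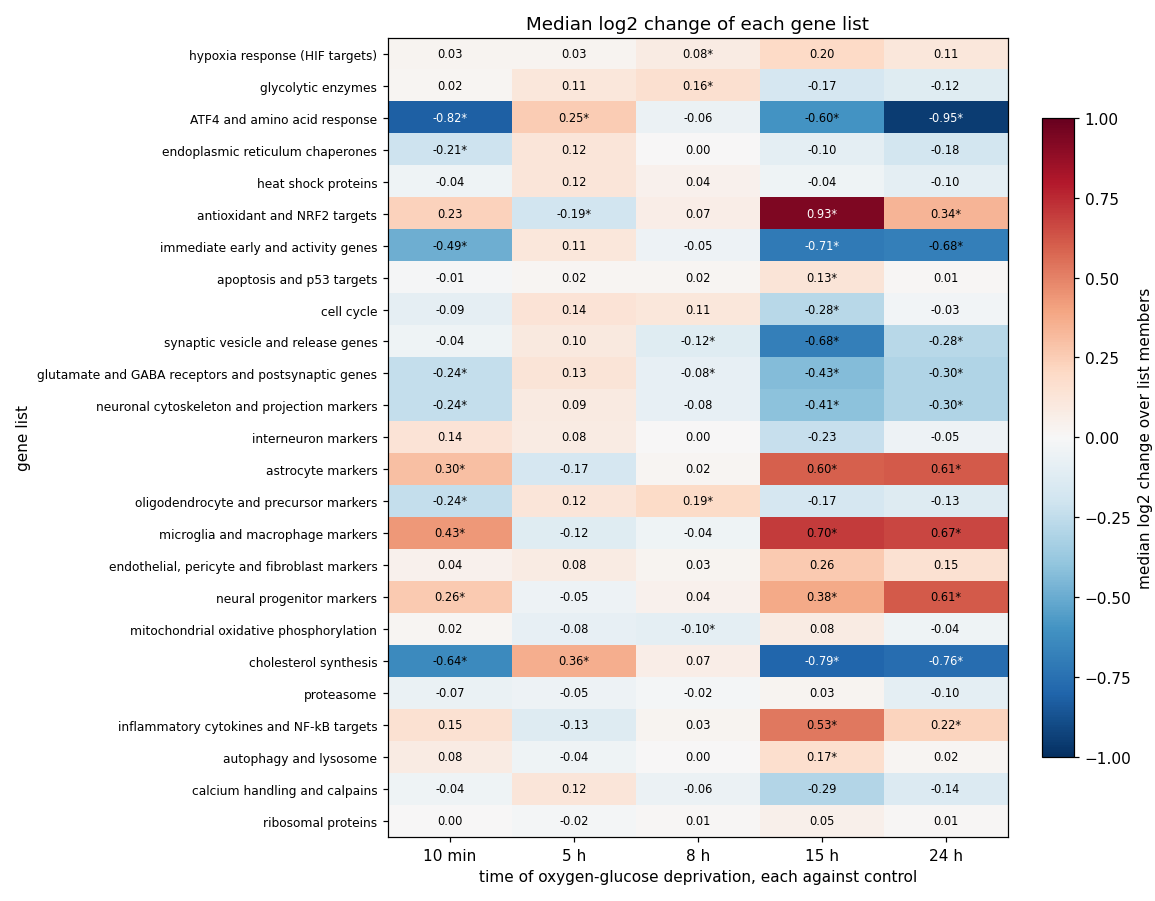
Median log2 change of the measured members of 25 gene lists at each time of OGD against the controls, in colour and digits; a star marks a camera adjusted p under 0.05 with the preset correlation. The ATF4 list was lowest at 24 h with -0.95 and the antioxidant list highest at 15 h with 0.93, and the direction of several lists at 5 h was opposite to that at 10 min. All times share the controls, and the rise of the ATF4 list at 5 h rests largely on control replicate 2, which lay low on it.

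After 24 h of OGD, the activity-induced, ATF4 and cholesterol genes remained below the controls, the astrocyte, microglia and progenitor markers above them, and the antioxidant genes were higher in fewer members. These are list tests with a preset correlation, and with an estimated one the progenitor list alone passed. Bdh2 rose by 2.43 ± 0.41 on the log2 scale (SE, n = 3 against 5, adjusted p = 0.000241), or 5.39-fold, Rnase1 4.96-fold, Ugt1a7c 4.50-fold and Plin4 4.44-fold. Fbxo2, a ubiquitin ligase subunit for glycoproteins, rose by 2.03, Acta2 by 2.02, Ccl9 by 1.98 and the matrix protein gene Prelp by 1.89. Fosb, Npas4 and the stress protein gene Nupr1 were not detected at 24 h and were at least 3.89-fold, 3.54-fold and 3.04-fold lower. Egr4 changed by -2.60, Dcn by -2.19, C2cd4a by -1.97, Lor by -1.73 and Asns by -1.71. Plin4 and Ccl9 were detected on 1 and Rnase1 and Nupr1 on 4 of 5 controls, and Egr4 on 1 of the 3 arrays at 24 h. For Nupr1 control replicate 2 read 5.01 against 7.05 ± 1.15 (SD, n = 5) for all controls. For Fosb it read 5.46, against 7.46 to 8.34 on the other controls and 4.46 to 4.52 at 24 h.

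Of the ATF4 and amino acid genes 19 of 23 fell and 1 rose at 24 h (19 and 1 adjusted over the list alone). Their median was -0.95 (adjusted p = 5.69e-10, adjusted p = 0.171 with an estimated correlation, and 8.63e-08 with a median of -0.67 with the block). Among them Atf5 changed by -1.38, Slc7a5 by -1.30 and Aars by -0.95. Cholesterol synthesis genes fell in 13 of 17 (14 adjusted over the list alone). Their median was -0.76 (adjusted p = 5.11e-08, adjusted p = 0.171 with an estimated correlation, and 8.63e-08 with a median of -0.70 with the block). Among them Mvd changed by -1.29, Lss by -1.21, Fdps by -1.12 and Hmgcs1 by -0.55. Immediate early and activity genes fell in 15 of 23 and rose in 1 (17 and 1 adjusted over the list alone). Their median was -0.68 (adjusted p = 7.25e-09, adjusted p = 0.109 with an estimated correlation, and 4.57e-09 with a median of -0.61 with the block). Among them Nptx2, detected on 1 of the 3 arrays, changed by -1.43 and Fosl2 by -0.88. On these 3 lists control replicate 2 lay at -0.76, -0.52 and -0.36.

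Astrocyte markers rose in 12 of 16 and fell in 1 at 24 h (13 and 1 adjusted over the list alone). Their median was 0.61 (adjusted p = 8.37e-07, adjusted p = 0.171 with an estimated correlation, and 8.63e-08 with a median of 0.65 with the block). Among them Gfap rose by 1.37, Apoe by 0.97, Clu by 0.92 and Vim by 0.69. Microglia and macrophage markers rose in 8 of 9 (9 adjusted over the list alone). Their median was 0.67 (adjusted p = 9.71e-06, adjusted p = 0.109 with an estimated correlation, and 4.39e-06 with a median of 0.60 with the block). Among them Lgals3 rose by 1.01, C1qc by 0.89, the lysozyme gene Lyz2 by 0.86 and Adgre1 by 0.75. Neural progenitor markers rose in 7 of 11 (8 adjusted over the list alone). Their median was 0.61 (adjusted p = 2.2e-05, adjusted p = 0.00737 with an estimated correlation, and 1.31e-06 with a median of 0.57 with the block). Among them Prom1 rose by 1.19, Notch1 by 0.84, Id4 by 0.80 and Id3 by 0.65. Antioxidant genes rose in 11 of 22 and fell in 2 (12 and 2 adjusted over the list alone). Their median was 0.34 (adjusted p = 0.00146, adjusted p = 0.418 with an estimated correlation, and 0.00218 with a median of 0.30 with the block). Among them the quinone reductase gene Nqo1 rose by 1.5, Gstm1 by 1.03, Gpx1 by 0.75 and Gstm5 by 0.40. Inflammatory genes rose in 3 of 10 (4 higher and 1 lower adjusted over the list alone). Among them Ccl4 rose by 1.29 and Vcam1 by 0.70, and Ccl3 was at least 1.05-fold higher (median 0.22, adjusted p = 0.0104, adjusted p = 0.171 with an estimated correlation, and 0.00555 with a median of 0.27 with the block). Nqo1, Adgre1 and C1qc were detected on 2 of 5 controls and Ccl4 on 3, and Ccl3 on 1 of the 3 arrays and no control. On these 5 lists control replicate 2 lay at 0.19, 0.14, -0.01, 0.36 and 0.05.

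Synaptic vesicle genes fell in 10 of 22 at 24 h (10 adjusted over the list alone). Their median was -0.28 (adjusted p = 0.000175, adjusted p = 0.171 with an estimated correlation, and 6.27e-06 with a median of -0.31 with the block). Among them Slc17a7 changed by -0.93, Sv2a by -0.84, Cplx1 by -0.73 and Rab3a by -0.48. Receptor and postsynaptic genes fell in 8 of 16 (9 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.00648, adjusted p = 0.171 with an estimated correlation, and 0.0214 with a median of -0.22 with the block). Among them Nrgn changed by -1.16, Camk2a by -0.91, Gria1 by -0.76 and Shank3 by -0.53. Neuronal cytoskeleton and projection genes fell in 12 of 25 (13 adjusted over the list alone). Their median was -0.30 (adjusted p = 0.000298, adjusted p = 0.171 with an estimated correlation, and 0.000417 with a median of -0.29 with the block). Among them Nefm changed by -0.81, Elavl3 by -0.80, Neurod2 by -0.74 and the tau gene Mapt by -0.63, while other probes of Sv2a and Mapt read -0.30 and -0.27. On these 3 lists control replicate 2 lay at -0.02, -0.14 and -0.18. Fos changed by -1.66, Hmox1 by -0.89, Cdkn1a by -0.64, Vegfa by -0.57 and Ddit3 by -0.39 (adjusted p = 3.88e-05, 0.00296, 0.0116, 0.00176 and 0.0332), and Slc2a1 differed by 0.33 (adjusted p = 0.162). The hypoxia list had a median of 0.11 and a mean of -0.02 (3 of 23 higher and 8 lower, 6 and 8 adjusted over the list alone, adjusted p = 0.964).

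In all, 1534 probes were higher and 1506 lower at 24 h (1243 and 1221 genes), of which 176 and 69 differed at least 2-fold. Blocking on the slide gave 802 and 644, and 1341 of these were shared, while Gstm5, Rab3a, Gria1, Elavl3, Mapt, C1qc, Hmox1, Ddit3 and Cdkn1a no longer passed (adjusted p = 0.0557 to 0.371). The authors' normalized values gave 964 higher and 1990 lower. Without 24 h replicate 3 the count was 1817.

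**Figure D3:**
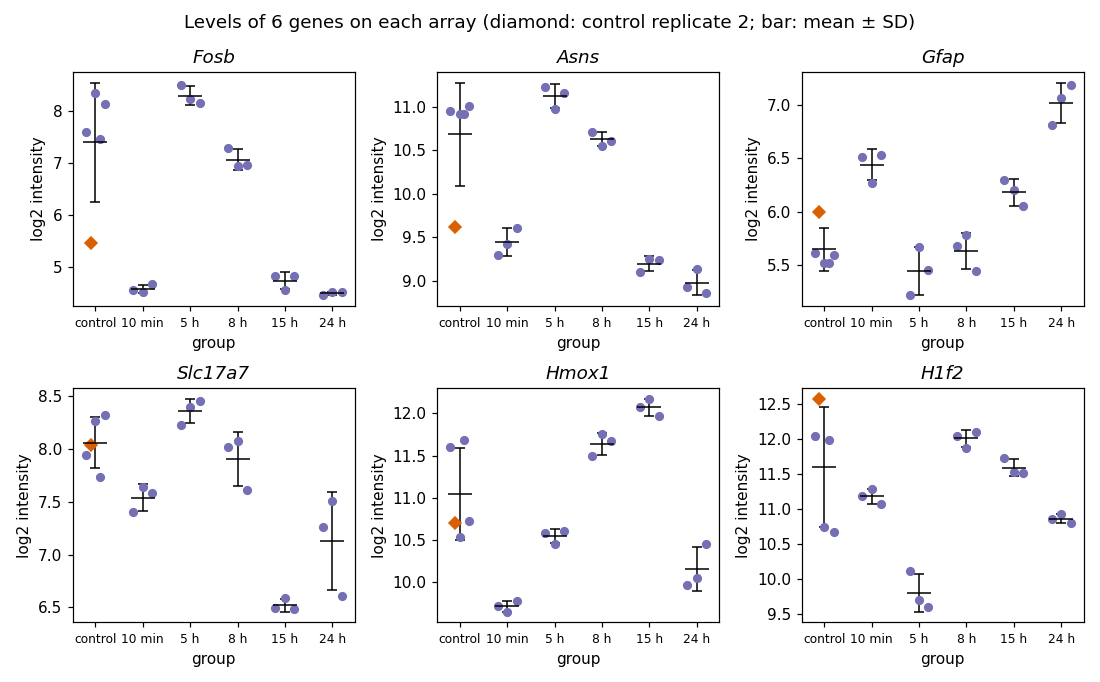
Normalized log2 intensity of 6 genes on each of the 20 arrays by group, with the mean and SD as bars and control replicate 2 as a diamond. Asns lay at 9.62 on control replicate 2, close to the 9.44 ± 0.16 (SD, n = 3) of the 10 min arrays, against 10.95 ± 0.05 (SD) for the other 4 controls.

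Between 5 h and 8 h of OGD, on 1 slide, histone genes led the rises. H1f2 rose by 2.21 ± 0.33 on the log2 scale (SE, n = 3 against 3, adjusted p = 0.00267), or 4.63-fold, and H2bc9, H2bc11 and H2bc7 by 1.79, 1.76 and 1.69. The small heat shock gene Hspb3 rose by 1.66. Ggct, which acts on gamma-glutamyl peptides, and the chromatin protein gene Dpf1 were not detected at 8 h and were at least 1.51-fold and 1.53-fold lower (other Ggct probes -0.32 and -0.33), and Hk1, detected on 1 of the 3 arrays at 8 h, changed by -0.98, the hyaluronan synthase gene Has3 by -0.90 and the tubulin gene Tuba3b by -0.83. Antioxidant genes rose in 3 of 22 (5 adjusted over the list alone, median 0.29, adjusted p = 0.000395, and adjusted p = 0.486 with an estimated correlation). Cholesterol synthesis genes fell in 1 of 17 (3 adjusted over the list alone, median -0.29, adjusted p = 0.00157, and adjusted p = 0.526 with an estimated correlation), and 0 of 23 ATF4 genes passed (0 adjusted over the list alone, median -0.34, adjusted p = 0.00157, and adjusted p = 0.526 with an estimated correlation). Synaptic vesicle, receptor, neuronal cytoskeleton and calcium handling lists had medians of -0.20, -0.21, -0.15 and -0.23 (adjusted p = 0.00154, 0.00555, 0.00336 and 0.00924, and adjusted p = 0.415 for each with an estimated correlation), with 0 members past the test and 1, 1, 2 and 0 lower adjusted over the list alone. Astrocyte markers had a median of 0.27 with 0 of 16 past the test (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0163, and adjusted p = 0.526 with an estimated correlation). In fry the antioxidant, cholesterol, ATF4, synaptic vesicle, cytoskeleton and astrocyte lists did not pass (adjusted p = 0.0675, 0.162, 0.246, 0.061, 0.061 and 0.135). In all 129 probes were higher and 112 lower (225 and 213 with the slide as a block). The authors' normalized values, which shift the median probe by -0.11 here, gave 63 higher and 717 lower, and of these 780 calls 172 were shared with the 241. Without 5 h replicates 2 or 3 or 8 h replicates 1 or 2 the counts were 31, 23, 27 and 22.

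Between 8 h and 15 h of OGD the clock-controlled gene Dbp rose by 2.95 ± 0.43 on the log2 scale (SE, n = 3 against 3, adjusted p = 6.74e-05, 0.0943 with the slide as a block) and Bdh2 and Rnase1 rose by 2.67 and 2.33 (adjusted p = 0.14 and 0.0709 with the block). Plin4 and Pvalb, not detected at 8 h, were at least 5.46-fold and 5.42-fold higher, and Fosb, not detected at 15 h, was at least 3.30-fold lower (adjusted p = 0.2 with the block). C2cd4a changed by -2.26 and the phosphoprotein gene Arpp21 by -2.07 (another probe -0.76). The synaptic pentraxin gene Nptx2 changed by -1.97 and the secretogranin gene Scg2 by -1.84. Antioxidant genes rose in 18 of 22 (19 adjusted over the list alone, median 0.77, adjusted p = 1.54e-09, and adjusted p = 0.0743 with an estimated correlation), astrocyte markers in 13 of 16 (13, median 0.58, adjusted p = 2.14e-06, and adjusted p = 0.0768 with an estimated correlation) and microglia markers in 8 of 9 (9, median 0.75, adjusted p = 4.91e-05, and adjusted p = 0.0743 with an estimated correlation). Synaptic vesicle genes fell in 14 of 22 (17 adjusted over the list alone, median -0.54, adjusted p = 1.27e-06, and adjusted p = 0.0743 with an estimated correlation), cholesterol genes in 14 of 17 (14, median -0.79, adjusted p = 3.37e-07, and adjusted p = 0.134 with an estimated correlation) and activity genes in 16 of 23 (16, median -0.69, adjusted p = 2.14e-06, and adjusted p = 0.0768 with an estimated correlation). These 6 medians were, with the slide as a block, 0.69, 0.58, 0.59, -0.50, -0.60 and -0.56 (adjusted p = 2.54e-08, 1.06e-05, 0.000108, 3.8e-07, 7.44e-05 and 7.09e-05). Oxidative phosphorylation genes rose in 12 of 35 (12 adjusted over the list alone, median 0.19, adjusted p = 0.00121, adjusted p = 0.0743 with an estimated correlation, and 0.00246 with a median of 0.14 with the block). Neural progenitor markers rose in 7 of 11 (7 adjusted over the list alone, median 0.41, adjusted p = 0.00285, and adjusted p = 0.0743 with an estimated correlation) and inflammatory genes in 6 of 10 (6, median 0.56, adjusted p = 0.000901, and adjusted p = 0.0743 with an estimated correlation). Autophagy genes rose in 9 of 22 and fell in 3 (10 and 4 adjusted over the list alone, median 0.30, adjusted p = 0.0227, and adjusted p = 0.0743 with an estimated correlation), and apoptosis genes rose in 5 of 20 (5, median 0.14, adjusted p = 0.0291, and adjusted p = 0.0743 with an estimated correlation). Neuronal cytoskeleton genes fell in 13 of 25 and rose in 1 (14 and 1 adjusted over the list alone, median -0.37, adjusted p = 0.000235, and adjusted p = 0.0917 with an estimated correlation), and oligodendrocyte markers fell in 6 of 9 (6, median -0.61, adjusted p = 0.00683, and adjusted p = 0.0768 with an estimated correlation). The ATF4, cell cycle and receptor lists, with medians of -0.54, -0.39 and -0.24 (adjusted p = 0.00322, 0.00406 and 0.0286), passed neither with an estimated correlation (adjusted p = 0.475, 0.417 and 0.24 with an estimated correlation) nor with the slide as a block (adjusted p = 0.852, 0.398 and 0.209). In all 1674 probes were higher and 1761 lower, and with the slide as a block, which sets each time against the controls of its own slide, 337 and 363.

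Between 15 h and 24 h, on 1 slide, antioxidant genes fell and synaptic vesicle genes rose as lists with a preset correlation. With an estimated correlation these lists had adjusted p = 0.0551 and 0.0695. Hmox1 changed by -1.92 ± 0.23 on the log2 scale (SE, n = 3 against 3, adjusted p = 0.000316), the sulfiredoxin gene Srxn1 by -1.64, the immunity-related GTPase gene Igtp by -1.72 and the oocyte protein gene Ooep by -1.94, and the glutathione transferase gene Gsta1, not detected at 24 h, was at least 2.22-fold lower. Necab1, a calcium-binding protein gene, rose by 1.37, Nts by 1.07, the intermediate filament gene Synm by 0.94, Prss12 by 0.90 and the neuronal calcium sensor gene Vsnl1 by 0.89. Prss12 was detected on 1 of the 3 arrays at 15 h and Ooep on 2 of the 3 at 24 h. Antioxidant genes fell in 5 of 22 (10 adjusted over the list alone, median -0.32, adjusted p = 1.15e-13, and adjusted p = 0.0551 with an estimated correlation) and synaptic vesicle genes rose in 2 of 22 (10 adjusted over the list alone, median 0.25, adjusted p = 9.45e-08, and adjusted p = 0.0695 with an estimated correlation). Apoptosis and p53 genes fell in 4 of 20 (5 adjusted over the list alone, median -0.10, adjusted p = 0.00251, and adjusted p = 0.0323 with an estimated correlation) and autophagy genes in 1 of 22 (2, median -0.13, adjusted p = 0.00369, and adjusted p = 0.0323 with an estimated correlation). ATF4 genes fell in 3 of 23 (6 adjusted over the list alone, median -0.31, adjusted p = 2.44e-05, and adjusted p = 0.357 with an estimated correlation), and cell cycle genes rose in 1 of 27 (4, median 0.22, adjusted p = 0.000249, and adjusted p = 0.35 with an estimated correlation). Small shifts were also found for the hypoxia list, the neuronal cytoskeleton, oxidative phosphorylation and the proteasome, with medians of -0.03, 0.15, -0.09 and -0.09 (adjusted p = 0.0403, 0.0403, 0.0155 and 0.0154). These became adjusted p = 0.197, 0.357, 0.199 and 0.0551 with an estimated correlation, and 0.0523, 0.0523, 0.0201 and 0.019 with the block. The ATF4, cell cycle and cytoskeleton lists did not pass in fry (adjusted p = 0.145, 0.14 and 0.149). In all 45 probes were higher and 64 lower, and 103 and 113 with the slide as a block. Without 15 h replicates 1 or 3 the counts were 43 and 38, without 24 h replicates 1, 2 or 3 they were 23, 32 and 168, and 917 probes passed when the 2 times were fitted alone.

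The calls at 10 min, 15 h and 24 h overlapped. Of the probes called at both 10 min and 24 h, 824 were higher and 644 lower at both times and 2 opposite, where independent lists would share 169.3 and 141.4. At 15 h and 24 h, 1266 were higher at both, 1118 lower at both and 1 opposite (286.5 and 299.6 for independent lists), and at 10 min and 15 h 792 and 572, with 52 opposite (215.3 and 195.1). These comparisons share the controls, and unchanged groups simulated against the same controls gave a correlation of 0.38 across probes and a covariance of 0.0127. The simulation drew independent noise for each probe and held no array shifted across many probes. Its 0 shared calls were nearly fixed in advance, since unchanged groups are rarely called, and say nothing about the shared counts. Shared calls in the same direction with the slide as a block were 391, 1227 and 360, against 1468, 2384 and 1364 without it, and with split controls they ran from 134 to 1175, 1382 to 1812 and 123 to 1316. The observed correlations were 0.81, 0.85 and 0.65 and the covariances 0.105, 0.146 and 0.0961. With the controls split, so that each time was set against other controls, the correlations ran from 0.52 to 0.80, 0.59 to 0.83 and 0.40 to 0.66. Log2 changes at 5 h correlated at -0.27 with those at 10 min, at -0.33 with those at 15 h and at -0.38 with those at 24 h. With split controls these ran from -0.61 to 0.03, -0.60 to 0.01 and -0.66 to -0.14, so the sign held in every split only with 24 h. By the first time at which it passed, 2134 probes were first called at 10 min, 228 at 5 h, 0 at 8 h, 2532 at 15 h and 394 at 24 h, which makes 2362 early and 2926 late probes.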

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

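Of 179 control values tested, 36 had 1 array far from the other 4 by Dixon's ratio, where chance would give about 8.9, and 32 of these belonged to control replicate 2. Most of the values were levels of genes named for their differences in these same data. The 8.9 holds for values not chosen in this way, so part of the excess may come from the choice. Tests of the slide and of the position of control replicate 2 were chosen after the counts had been seen; the splits were planned before. Below the other controls, control replicate 2 stood apart on the list means of the ATF4 response (ratio 0.87), the cell cycle (0.84) and oligodendrocyte markers (0.923), and on Npas4 (0.788), C2cd4a (0.765), Atf5 (0.805), Dcn (0.868), Slc7a5 (0.89), Asns (0.926), Gria1 (0.719), Elavl3 (0.748), Bcl11b (0.756), Cldn11 (0.87), Lss (0.823), Cdkn1a (0.775), Lor (0.781), Nars (0.83), Mcm5 (0.747), Dpysl3 (0.771), Nupr1 (0.821), Sv2a (0.783) and Mapt (0.736). Above them it stood apart on Ccl9 (0.955), Acta2 (0.789), Plin4 (0.853), Gstt3 (0.86), Gfap (0.781), Adgre1 (0.892), Gstm5 (0.756), Fbxo2 (0.757), Prelp (0.711) and Gsta1 (0.715). The others were Fosl2 (0.722) and Ggct (0.744), low on control replicate 1, and Scg2 (0.838) and the share of probes detected (0.72), high on control replicate 4.

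The many probes changed at 10 min, 15 h and 24 h were weighed against the slide and against a culture state shared by a control. If the slide were the cause, few probes would pass with the slide as a block, and 2930 did at 15 h and 1446 at 24 h, of which 2640 and 1341 were among the calls without the block, so the slide alone does not account for these. At 10 min 1236 passed, but there the block sets 3 arrays against control replicate 1 alone and 749 were shared, so the slide was not excluded. Over the probes called without it, control replicate 2 lay at 0.83 of the way from the other controls to the 10 min arrays and at 0.68 to the 24 h arrays, while other controls treated the same way lay at most at 0.14 and 0.05. At 15 h it lay at 0.50, which did not decide. An untreated array thus carried part of the difference, consistent with a state of the culture or a handling step that does not need OGD, and which of these it was cannot be told from the arrays. Not all of it was shared: control replicate 2 lay at -0.02 on synaptic vesicle genes against -0.67 to -0.63 on the 15 h arrays, at 0.05 on inflammatory genes against 0.40 to 0.49 at 15 h, and at -0.01 on progenitor markers against 0.46 to 0.62 at 24 h. On other lists called at 15 h it lay beyond every 15 h array. These were the ATF4 list (-0.755 against -0.559 to -0.515) and the cell cycle list (-0.528 against -0.351 to -0.294). For these lists the untreated array differed at least as much as the 15 h arrays.

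In other splits of the same arrays, 10 min was matched or passed by 2 of 56 splits, the real one included (highest other 2674), and 15 h and 24 h by 1 of 56 each (2781 and 2586). The 2674 came from setting control replicates 3, 4 and 5 against the 10 min arrays joined with control replicates 1 and 2. At 5 h 3 of 56 splits gave as many (highest other 1218), so chance was not excluded there. At 8 h, where 0 probes passed, every split gives as many by construction and nothing was tested. Over all groups 1 of 100 splits reached the count (highest other 1455). For 8 h against 5 h, 15 h against 8 h and 24 h against 15 h, 1 of 10 splits did (highest others 0, 0 and 1), too few splits to exclude chance.

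Differences between times, tested directly, were 241 probes for 8 h against 5 h, 3435 for 15 h against 8 h and 109 for 24 h against 15 h, and between 15 h and 24 h the lists of apoptosis and p53 targets (median -0.10) and of autophagy and lysosome genes (median -0.13), which also passed with an estimated correlation.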

How the results depend on the processing

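No named gene or list that passed reversed its direction, except that 36 of the 78 called lists turned sign with the names of the processed tables. Those names were an alternative added after seeing the data. Genes that had not passed gave 16 reversed values, none of which passed. Slc2a1 at 10 min went from 0.45 to -0.05 and Cdkn1a at 15 h from -0.09 to 0 with the slide as a fixed block or slide-matched controls. Fos at 8 h went from 0.01 to -0.27 in these fits, -0.09 with the random slide block, -0.04 with 75th-percentile scaling, -0.01 with cyclic loess, -0.02 with the authors' values, -0.33 with array weights and -0.20 to 0.11 without single arrays. Cdkn1a at 8 h went from -0.20 to 0.01 with array weights and -0.40 to 0.15 without single arrays. Over all alternatives named genes gave 292 weaker, 13 stronger and 4994 unchanged results, lists 196 weaker and 1530 unchanged, and counts 70 moved and 153 unchanged. Counts stayed within 1.5 times with 75th-percentile scaling, cyclic loess, no background model, no filter, detection on all arrays of a group, and trend and robust moderation. With the slide as a fixed block, or with slide-matched controls (the same model), 1236 probes passed at 10 min, 0 at 5 h, 1446 at 24 h, 438 for 8 h against 5 h, 700 for 15 h against 8 h, 216 for 24 h against 15 h and 3238 as probes changed in any group. A random slide block (correlation 0.217) gave 84 at 5 h, 385 for 8 h against 5 h and 2097 for 15 h against 8 h. A replicate block gave 557 at 10 min and 1886 at 24 h, but the numbers do not pair samples: arrays with the same number had a mean correlation of -0.024 over 45 pairs and those with different numbers 0.014 over 120. The authors' normalized values gave 941 at 5 h, 780 for 8 h against 5 h and 57 for 24 h against 15 h. Array weights, which did not fully converge and ran from 0.178 to 5.61, gave 4550 at 10 min, 687 at 5 h, 584 at 8 h, 4878 at 24 h, 3583, 5782 and 1825 between successive times and 8721 in any group. Fits of only the groups compared gave 582 at 10 min, 0 at 5 h, 1988 at 24 h and 917 for 24 h against 15 h. These fits have fewer samples and also take the spread from the groups compared alone. The main fit shares its estimate over all 6 groups, although the median SD was 0.196 among the controls and 0.102 to 0.143 within the times. The counts against the controls thus depend on sharing the spread. A fold of at least 1.5 left 705, 104, 1589 and 1110 at 10 min, 5 h, 15 h and 24 h, 129 for 8 h against 5 h, 1527 for 15 h against 8 h and 2051 in any group, and an adjusted p under 0.01 left 790, 23, 2674 and 1760, and 24, 2094 and 33 between successive times; these are stricter by construction. Leaving out 5 h replicate 1 and 8 h replicate 3 together, an alternative chosen after seeing the data, gave 97 for 8 h against 5 h. Leaving out each array in turn gave 1111 (without 10 min replicate 2) to 3532 (without control replicate 2) at 10 min, 27 (without 5 h replicate 2) to 551 (without control replicate 5) at 5 h, 0 to 1 (without control replicate 4) at 8 h, 3120 to 4744 at 15 h, 1817 (without 24 h replicate 3) to 4075 at 24 h, 22 (without 8 h replicate 2) to 312 for 8 h against 5 h, 2680 to 3029 for 15 h against 8 h, 23 (without 24 h replicate 1) to 168 (without 24 h replicate 3) for 24 h against 15 h and 5038 to 6422 in any group. The cause of the other shifts was not tested. Of 78 list calls 4 held with an estimated correlation, and with fry 61 held and 17 did not. Fry also passed lists that camera did not: at 10 min the interneuron, vascular, proteasome and autophagy lists (adjusted p = 0.00743, 0.0293, 0.0293 and 0.0135), at 5 h apoptosis (0.0453), at 15 h oxidative phosphorylation (0.00797), and at 24 h the oligodendrocyte, vascular, proteasome and autophagy lists (0.00296, 0.0107, 0.0102 and 0.00319). Between times these were apoptosis and progenitor lists for 8 h against 5 h (0.0264 each) and glycolysis, interneuron, vascular and proteasome lists for 15 h against 8 h (0.0158, 0.00232, 0.0342 and 0.0375). Camera too passed lists in some alternatives that had not passed. At 10 min these were the cell cycle list, lower (adjusted p = 0.0323 with the slide block, 0.00117 without control replicate 2), and the antioxidant list, higher (0.00739 to 0.046, among them without control replicate 2 and with the authors' values). At 5 h the cell cycle list was higher (0.00568 to 0.0465) and the astrocyte list lower (0.00941 to 0.0465), each in several alternatives. The cell cycle list was also higher at 8 h in several (0.00348 to 0.0466), and the ATF4, antioxidant and cytoskeleton lists passed at 8 h with the random slide block (0.029, 0.029 and 0.0335). Other lists passed in fewer alternatives, at 5 h among them the cytoskeleton, glycolysis and synaptic vesicle lists, higher, and the microglia, oxidative phosphorylation and ribosomal lists, lower. Each array had 37% to 40.9% of probes detected, and probes detected on fewer than 3 arrays were tested only without the filter.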

Other observations

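Histone genes led the falls at 5 h of OGD and the rises from 5 h to 8 h. Of 39 histone probes, a group chosen after the leading genes had been seen and not tested as a list, 18 were lower at 5 h than in the controls (median -0.47) and 18 were higher at 8 h than at 5 h (median 0.61). At 8 h against the controls 0 passed, with a median of 0.11. With the slide as a block 0 probes of any kind passed at 5 h. At 10 min 3 histone probes were lower and 3 higher (median -0.26), at 15 h 9 were lower and 2 higher (median -0.15), at 24 h 8 lower and 1 higher (median -0.34), and at 15 h against 8 h 10 lower and 1 higher (median -0.24). Most such histone transcripts are made during DNA replication and lack a poly(A) tail. The mean over these probes was -0.62, -0.68 and -0.66 on the 5 h arrays, 0.17, 0.16 and 0.00 on the 8 h arrays, and 0.18, 0.18, -0.20, 0.07 and -0.23 on controls 1 to 5, relative to the control mean.

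Predictions for list calls with the processed tables' names, and for the level and scaling of the hypoxia list, were recorded as written before their tests. The alternative with the processed tables' names was itself added after the data had been seen, and the hypoxia tests address a result already seen. The correlation of 2 probes of a gene was also chosen after. At 15 h 0 lists passed camera with the names of the processed tables, and the 2 probes of a gene correlated at 0.337 with the profile's names against 0.062, so the processed tables' names are likely the misplaced ones. In camera the hypoxia list was not raised at 10 min, 5 h, 15 h or 24 h, while fry called it raised at 15 h (adjusted p = 0.0155). The median level of its measured members was 7.95 (lower quartile 5.95) against 7.5 for all tested probes, so most measured members did not sit near background. Members detected too rarely to be tested, such as Bnip3, were not counted. With 75th-percentile scaling the list's median change reached at most 0.14, so no larger rise appeared with that scaling either. No biological explanation was tested.

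The Pop4 probe read 4.53 to 4.56 on the 10 min arrays, but also 4.48 on 5 h replicate 1, 4.43 on 8 h replicate 2 and 4.49 on 15 h replicate 1, and 9.79 to 10.64 on all others. The Psmc1 probe read 7.99 to 8.39 at 15 h, 5.38 to 6.07 on the controls, 5.26, 8.12 and 5.21 at 10 min, 6.60, 6.92 and 7.81 at 5 h, 5.35, 5.55 and 8.25 at 8 h, and 5.53, 7.83 and 7.85 at 24 h. The Plek probe read 6.86, 4.31 and 8.25 on the 15 h arrays, 7.18 on 24 h replicate 3 and 4.31 to 4.52 on all others.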
